A study of Homo sapiens with 4 samples.

How the data were processed

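RNA immunoprecipitation followed by sequencing was done in HK-2 cells, with 2 PARP1 IPs and 2 inputs. Per the labels' protocols, lysates were cleared on protein G beads and incubated with beads carrying a Flag antibody, the beads were washed 6 times, and libraries for paired-end sequencing were made by random-primed reverse transcription and amplification. The protocols describe no crosslinking step. Per the submitters' processing notes, bcl2fastq and TopHat2 were used and the build was GRCh38. Versions, settings, the program that called the sites, its thresholds and any removal of duplicate reads are not given in the sources used here.

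The deposited values are whole-number counts of tags over a site (k) and of mutated tags (m), per the file headers, with 1 list for each IP. Per the file headers the authors also gave each site an FDR, a p-value type of measure, which was the same for all sites of 1 list with the same mutation type, k and m. Every site was 1 base long, m was at least 2, and the deposited score equalled m. The region of a site and its gene identifier were taken from the lists. Because the lists hold mutated bases and not the peak intervals the analysis was designed for, each site was treated as a peak of 1 base. Overlap meant the same base and strand. Amplified reads without molecular identifiers are not independent molecules, and a site can be listed only where tags carry a mismatch, so a transcript with many tags and no mismatch has no site. Where reads map to several places, as at pseudogenes and gene families, the lists do not say how they were assigned. Depth is known only as tags over listed sites, which is not the depth of the library.

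Gene coordinates, spans and classes came from GENCODE release 29 (GRCh38, counted from 1). Of the genes named, 16187 identifiers of IP 1 and 18201 of IP 2 were in it. Of 548 members of 16 gene lists fixed before the data were examined, 2 had no match (H3C2 and H3C3) and were left out. A gene counted as named when a list assigned it a site on either strand. Each list was compared with all other genes of its class (19951 protein-coding or 22092 noncoding genes in all) by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 16 lists and a threshold of 0.05. It was also placed among 10000 random lists matched on gene span in 10 bins, which gave the two-sided permutation p, adjusted likewise. The percentile was fixed beforehand and its use as a test was added after the data were seen. Chance overlap of sites came from 100 random placements. Percentiles of a gene are of its sense sites per 10 kb, among protein-coding genes of the same span bin. Genes named for a shared site were picked from the same sites, which can raise their percentiles, so these percentiles test nothing about a list. Intervals are exact (Clopper-Pearson) at 95%.

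On simulated data over 19951 genes (200 simulations, lists of 50 genes), lists raised by an odds factor of 4 were called in 94.5% of cases by Fisher's test and 96.5% by span matching. Lists of long genes with no effect were called in 98.5% of cases by Fisher's test and 2.5% by span matching, so both results are given for every list. Apart from the raised lists, span alone set the simulated chance of a gene. These rates therefore do not cover lists that differ in transcription. A simulated set of 5000 shared sites was recovered in full (5000), which checks only the matching of positions.

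The rule for named genes, fixed beforehand, took the 10 genes whose best shared site had the largest score (the smaller of the 2 IPs), the 10 with the most shared sites, up to 4 genes with a shared site and up to 2 with no site in each list, PARP1, the 5 strongest intergenic sites, and for each IP the 3 genes with the strongest site among genes named in that IP alone. The best shared site of a gene was the one with the smallest FDR, taking the larger of the 2 IPs, with ties broken by mutated tags and then by tags. Of the intergenic sites, tag counts are given and positions are not. The values of 1 gene that the rule takes are not reported here. COL4A3, COL4A4, COL4A5, FN1, CCN2, MALAT1, HAVCR1, PAX8, NRXN3, NLGN1, RIMS2, MT-ND4, MT-ND5, MT-CO3 and the genes of the chromosome 17 region stand outside the rule and were chosen after their values were seen.

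Alternatives fixed beforehand were a stricter threshold, other placements, overlap without strand, equal numbers of sites, shared sites only, another background for the lists, and leaving out each IP. The planned upper part of each list by score was replaced by the sites with an FDR below the most common one, because 65.6% of sites of IP 1 and 66.5% of IP 2 tie at that value. The tied sites are the substitutions with 2 tags, both mutated (109035 in IP 1 and 152722 in IP 2). The 57029 and 76380 sites below that FDR are therefore mostly deletions and insertions. This setting changes the mix of mutation types as well as the strictness. Alternatives added after the data were seen were sense sites, exon sites, matching of mutation type, a window of 10 bases, sites with 4 or more mutated tags, local shifts the span-matched test under each alternative and the comparison of the matrix lists with other lists. The fold of IP over input was left out because the lists hold no input values, and GC content because no genome sequence was used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.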

Results

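RNA recovered with PARP1, the nuclear enzyme that attaches ADP-ribose chains to proteins at DNA breaks, was sequenced from HK-2 cells, an immortalised human proximal tubule epithelial line. The series title places the work on PARP1 and matrix genes in renal tubular cells. It holds 4 samples, of which 2 are PARP1 immunoprecipitations with a Flag antibody (IP 1 and IP 2) and 2 are inputs, with no control IP. The values analysed are 2 lists of sites, 1 for each IP, and the inputs were not analysed here. Each site is 1 base on 1 strand of GRCh38, with the number of sequenced tags over it, the number of those tags that carry a mutation, the authors' false discovery rate (FDR) and a gene. The lists are therefore lists of mutated bases rather than of peak intervals, and the values at a site are the authors'. Nothing in the labels says that the 2 IPs came from separate cultures, so the spread between them can be technical, and the 95% exact binomial intervals below cover counting error only.

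IP 1 listed 166248 sites and IP 2 listed 229782. Substitutions made up 72.5% of the sites in IP 1 and 73.5% in IP 2, deletions 21.8% and 21.05%, and insertions 5.68% and 5.47%. The tags over all sites summed to 419675 in IP 1 and 572870 in IP 2. The depth per site was low, with a median of 2 tags and a median of 2 mutated tags in both lists. Sites with 2 tags, both mutated, made up 82.7% of IP 1 and 83.3% of IP 2, and sites with 10 or more tags made up 1.06% and 0.984%. The sources do not say whether the 2 tags of such a site come from separate fragments. Substitutions with 4 of 4 tags mutated numbered 3461 in IP 1 and 4915 in IP 2, against 4453 and 6265 with 3 of 3 and 610 and 813 with 5 of 5. The lists hold only sites that passed the authors' threshold, and the highest FDR was 0.00909 in IP 1 and 0.00926 in IP 2.

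The first comparison asked how far the 2 IPs list the same bases. At the same base and strand, 6935 sites of IP 1 (4.17%, interval 4.08 to 4.27) were also in IP 2, and 6941 sites of IP 2 (3.02%, interval 2.95 to 3.09) were also in IP 1. Sites in 5′ untranslated regions (UTRs) of IP 1 recurred at 9.51% (interval 7.43 to 11.9) and exons of noncoding genes at 8.97% (7.69 to 10.4), with overlapping intervals, 3′ UTRs at 6.36% and coding sequence at 5.70%. Intronic sites of IP 1 recurred at 4.71%, intergenic sites at 2.55% and sites antisense to a gene at 2.40%. Recurrence was higher at sites with more mutated tags. It was 3.44% in IP 1 and 2.39% in IP 2 at sites with 2 mutated tags, against 13.5% and 11.04% at sites with 4 or more, each set against the whole of the other list. With 4 or more mutated tags required in both lists the shares were 4.04% and 2.83%. When the sites of IP 1 were placed at random within the same gene, or within the chromosome where no gene was given, a mean of 0.0153% fell on a site of IP 2 and the highest of 100 placements gave 0.0253%. Bases of IP 1 were also listed on the opposite strand in IP 2, at 2031 sites (1.22%).

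**Figure D1:**
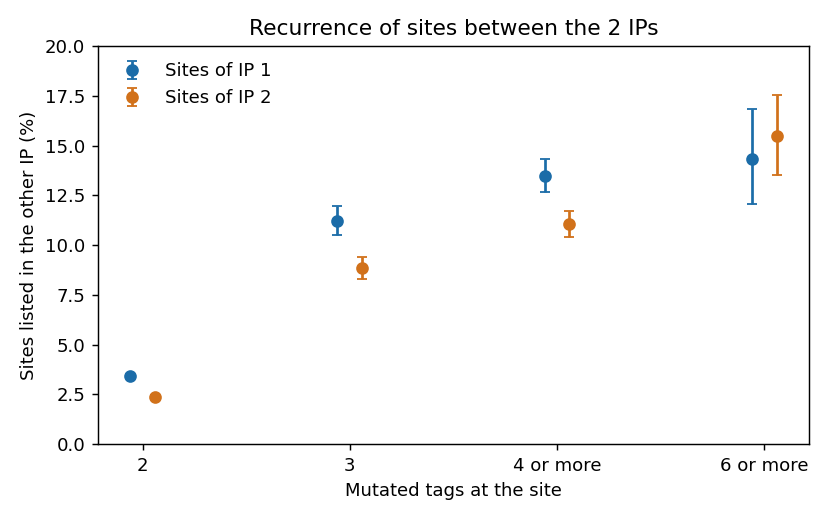
Share of the sites of each PARP1 IP that were listed at the same base and strand in the other IP (percent), by the number of mutated tags at the site, where the class of 6 or more is part of the class of 4 or more. Points are shares and bars are 95% exact binomial intervals; the share was 3.44% (IP 1) and 2.39% (IP 2) at 2 mutated tags and 14.3% and 15.5% at 6 or more.

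Across the shared sites, the tags over a site had a Spearman rho of 0.290 and a Pearson r of 0.825 between the IPs. For the mutated tags rho was 0.216 and r was 0.279, and for the FDR rho was 0.311. These are correlations across 6935 sites, which are not independent replicates, and 5252 of them had the minimum of 2 mutated tags in IP 1. Among shared sites with an FDR below the most common of each list, rho of the mutated tags was 0.650. That filter depends on the mutated tags and the mutation type, so 0.650 does not show better agreement at stronger sites.

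The second comparison placed the sites on transcripts. Introns held most sites, 62.3% in IP 1 and 55.6% in IP 2 by the authors' annotation. Intergenic sequence held 21.1% and 26.3%, and sequence antisense to a gene held 9.71% and 12.3%. The 3′ UTRs held 3.04% and 2.58%, coding sequence 2.39% and 1.88%, noncoding exons 1.07% and 0.938%, and 5′ UTRs 0.417% and 0.321%. Among sites with an FDR below the most common, which are mostly deletions and insertions, 3′ UTRs held 5.47% and 4.84% and coding sequence 4.28% and 3.45%. Among sites of IP 1 that were also in IP 2, introns held 70.4% (interval 69.3 to 71.5), all exon classes together 11.2% (10.4 to 11.9) and intergenic sequence 12.9% (12.1 to 13.7). Per megabase of the GENCODE release 29 annotation, 3′ UTRs held 157.0 sites in IP 1 and 182.3 in IP 2, which is 2.45 and 2.28 times the density of introns. Coding sequence held 1.92 and 1.69 times the intron density and 5′ UTRs 2.01 and 1.63 times. The class read from that annotation matched the authors' class for 93.7% of sites in IP 1 and 94.3% in IP 2.

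**Figure D2:**
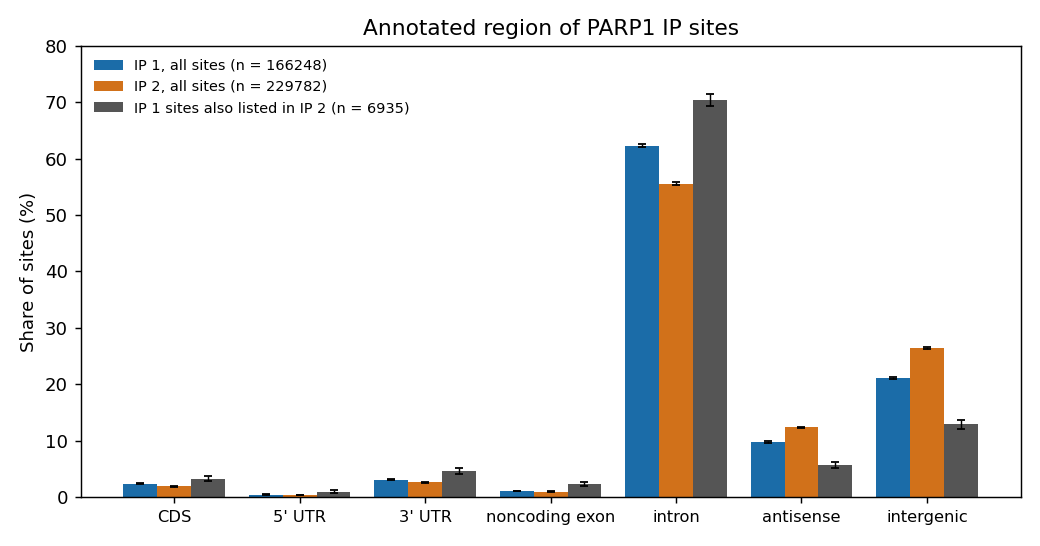
Share of sites (percent) in each annotated region for all sites of IP 1, all sites of IP 2 and the IP 1 sites that were also listed in IP 2. Bars are shares with 95% exact binomial intervals; introns held 62.3%, 55.6% and 70.4% and intergenic sequence 21.1%, 26.3% and 12.9%.

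The IPs shared a larger percentage of named genes than of bases, but these are unlike units. Against random placement within the gene, the share of bases found in both was 273 times as high. IP 1 named 16330 genes and IP 2 named 18371, and 13789 genes were in both, against 5108 for independent lists of these sizes drawn from the 58735 annotated genes. The 13789 were 84.4% of the genes of IP 1 and 75.1% of those of IP 2, and with an FDR below the most common 7530 genes were named in both. Protein-coding genes made up 11056 of the shared genes, 55.4% of all protein-coding genes, and noncoding genes 2085, or 9.44% of their class. A sense site at the same base in both IPs was found in 3132 genes. Gene span went with being named: 5.61% of protein-coding genes in the shortest of 10 span bins (median 1.93 kb) were named in both IPs, against 92.2% in the longest bin (median 262 kb). Across genes, the number of sense sites had a Spearman rho of 0.837 between the IPs, and the number per 10 kb a rho of 0.689. With no input values in the lists, how strongly each gene is transcribed is not separated from how often it is named.

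By FDR and then by the smaller number of mutated tags in the 2 IPs, the strongest shared site in a gene lay in the coding sequence of PXDN. It had at least 9 mutated tags in each IP. PXDN (chromosome 2, 1631887 to 1744852, minus strand) encodes peroxidasin, a matrix enzyme that crosslinks collagen IV. Shared sites with at least 7 mutated tags lay in the 3′ UTR of H2AX, the histone variant phosphorylated at DNA breaks (chromosome 11, 119093854 to 119095467), and in an intron of NALF1 (chromosome 13, 107163510 to 107866735). GFRA1, a co-receptor for glial cell line-derived neurotrophic factor (chromosome 10, 116056925 to 116273467), had a shared 3′ UTR site with at least 6 mutated tags. So did the 5′ UTR of UGCG, the ceramide glucosyltransferase, the 3′ UTR of NCLN and the coding sequence of FHL2. The other genes among the strongest 10 were MICOS10-NBL1, PCGF3-AS1 and the unnamed gene ENSG00000272822, with at least 7 mutated tags each. These 3 and their neighbours overlap, so a site can belong to another gene. The smaller tag total of the 2 IPs was 12 at MICOS10-NBL1, 11 at PXDN, 10 at FHL2 and 9 at UGCG. It was 8 at NCLN and PCGF3-AS1, 7 at H2AX and NALF1, 18 at ENSG00000272822 and 25 at GFRA1. At every site but those of ENSG00000272822 and GFRA1, most tags were mutated in the IP with fewer tags. The ranking by mutated tags does not measure binding.

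The genes with the most shared sites were mostly long, and the strongest shared site of each lay in an intron. WWOX, an oxidoreductase gene that spans a common fragile site (chromosome 16, 78099413 to 79212667), had 28 shared sites and SMYD3, a lysine methyltransferase gene (chromosome 1, 245749342 to 246507312), had 22. DOCK1, a Rac exchange factor, and KCNMA1, a calcium-activated potassium channel, had 15 each. ATXN1, the receptor tyrosine kinase EPHB2, MDGA2 and ZNF787 had 13 each, and the demethylase PHF2 and the phosphatase PTPRG had 12 each. WWOX carried 362 sense sites in IP 1 and 418 in IP 2, a density of 3.25 and 3.75 per 10 kb. The shorter ZNF787 (33915 bases) carried 28 and 38, a density of 8.26 and 11.2 per 10 kb.

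For the matrix, the question was whether matrix genes are named in both IPs more often than other protein-coding genes. Collagen genes were named in both in 23 of 28 cases (82.1%), against 55.4% of other protein-coding genes (adjusted p = 0.00903, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 16 lists). The basement membrane chains COL4A1 and COL4A2, neighbours on chromosome 13 (110148963 to 110307233 and 110305812 to 110513209), carried 49 and 75 sense sites in IP 1 and 65 and 83 in IP 2. By sense sites per 10 kb, as for all gene percentiles below, they were at percentiles 97.6 and 99.4 of genes of like span in IP 1. In IP 2 they were at 99.0 and 99.6. Genes picked for a shared site can have raised percentiles through that choice. COL18A1 had 27 and 38 sense sites, 10 of them in exons in each IP, and 10 sites were shared. COL6A2 had 11 and 9. COL18A1 was at percentiles 94.5 and 97.7 in IP 1 and IP 2, and COL6A2 at 93.2 and 84.9. The fibrillar chains COL1A2 and COL3A1 were named in neither IP. Other collagen IV chains did not follow COL4A1 and COL4A2. COL4A3 was also named in neither IP. COL4A4 had 0 and 1 sense sites (percentiles 5.7 and 11.9), and COL4A5 had 7 and 4 over 257702 bases. Random lists of the same span had a mean of 81.5% of genes named in both, and the collagens were at percentile 52.1 among them (permutation adjusted p = 1.0).

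Matrix glycoproteins and proteoglycans were named in both IPs in 42 of 51 cases (82.4%, Fisher's exact adjusted p = 0.000507). Their share also exceeded that of span-matched lists, whose mean was 64.6% (permutation adjusted p = 0.00512). The excess was 8.48 points with a shared site required and 12.3 points against genes named in either IP, where it was not called (permutation adjusted p = 0.287 and 0.0922). LAMA5, a laminin chain of basement membranes (chromosome 20, 62307955 to 62367312), had 32 sense sites in IP 1 and 62 in IP 2, percentiles 99.7 and 100.0 for its span. The heparan sulfate proteoglycans HSPG2 and AGRN had 38 and 16 in IP 1 and 34 and 25 in IP 2, and the proteoglycan VCAN 18 and 27. FN1, the fibronectin gene, had 20 and 18, and CCN2, a connective tissue growth factor, 2 and 2. FN1 and CCN2 are named outside the rule for named genes, after their values were seen. DCN and POSTN were named in neither IP.

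Matrix-modifying enzymes and their inhibitors were named in both IPs in 36 of 47 cases (76.6%, Fisher's exact adjusted p = 0.00834), against a span-matched mean of 58.8% (permutation adjusted p = 0.0174). That excess over span was not called with IP 2 alone (permutation adjusted p = 0.0772), with a shared site required (0.0576) or against genes named in either IP (0.113). The lysyl oxidase LOXL2 (chromosome 8, 23297189 to 23425328) had 47 sense sites in IP 1 and 63 in IP 2. The collagen lysyl hydroxylase PLOD2 had 25 in each, and the metalloproteinase ADAM12 had 65 and 53. PXDN, which held the strongest shared site, had 11 and 23. Percentiles for span in IP 1 and IP 2 were 98.8 and 99.7 for LOXL2 and 95.5 and 92.6 for PLOD2. They were 88.8 and 76.2 for ADAM12 and 63.2 and 84.8 for PXDN. The collagenase MMP1 and the stromelysin MMP3 were named in neither IP.

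Integrin and focal adhesion genes were named in both IPs in 33 of 37 cases (89.2%, Fisher's exact adjusted p = 0.00013). Against span-matched lists, with a mean of 75.1%, the permutation adjusted p was 0.0675. The excess over span of 14.1 points was called with exon sites only (25.8, permutation adjusted p = 0.0032) and with a shared site required (25.1, 0.0096), and fell to 8.82 with IP 2 alone (0.261) and 8.48 against genes named in either IP (0.291). PTK2, the focal adhesion kinase, had 87 sense sites in IP 1 and 78 in IP 2, and the actin linkers VCL and ACTN4 had 28 and 29 in IP 1 and 33 and 45 in IP 2. TNS1, a tensin, had 40 and 26. Percentiles for span in IP 1 and IP 2 were 96.5 and 91.6 for PTK2 and 91.6 and 92.4 for VCL. They were 97.1 and 99.6 for ACTN4 and 88.5 and 68.3 for TNS1. ITGA10 and DDR1 were named in neither. DDR1 lies in a stretch of chromosome 6 where 116 protein-coding genes in a row had no site.

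Genes of TGF-beta signalling were named in both IPs in 25 of 31 cases (80.6%, Fisher's exact adjusted p = 0.0108), and against span-matched lists (mean 68.0%) the permutation adjusted p was 0.128. With IP 2 alone the excess over span fell from 12.6 to 4.56 points (permutation adjusted p = 0.757). SMAD3, a transcription factor activated by TGF-beta receptors (chromosome 15, 67063763 to 67195195), had 70 sense sites in IP 1 and 54 in IP 2, percentiles 99.9 and 99.1 for its span. The receptor gene TGFBR2 had 12 and 22, the SMAD repressor SKIL 8 and 10, and SMAD4 1 and 2. Their percentiles in IP 1 and IP 2 were lower, at 71.8 and 88.1, 84.2 and 87.2, and 25.9 and 32.0. SNAI2 and TWIST1 were named in neither, although the annotated span of TWIST1 held 2 and 12 sense-strand sites that the lists do not assign to it.

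The 4 matrix lists were then set against the other protein-coding lists, a comparison chosen after the lists were seen. The matrix lists together (163 genes) were named in both IPs in 82.2% of cases and all other lists together (351 genes) in 63.8%, which is 14.0 and 15.0 points above genes of the same span. The difference in excess of -0.999 points had p = 0.432 in a two-sided permutation test within span deciles (100000 resamples). With sense sites only it was -0.862 points (p = 0.631, permutation test), and with exon sites only the matrix lists stood 12.3 points higher (p = 0.0175, permutation test). The p-values of these comparisons are not adjusted for their number. The matrix lists were first compared with the DNA repair, splicing and housekeeping lists alone (112 genes), which were picked after their own excess over span was seen, so the p-values of that comparison carry no weight. Those lists stood 24.9 points above genes of the same span, and the matrix lists differed from them by -10.95 points (p = 0.103, permutation test). With sense sites only the difference was -16.2 points (p = 0.0124, permutation test), and with exon sites only -2.08 points (19.4 against 21.5, p = 0.490, permutation test).

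PARP1 itself was named in both IPs. The IPs used a Flag antibody. At exon sites the lists do not separate RNA of the gene from RNA of a tagged copy, if one was introduced. The gene (chromosome 1, 226360691 to 226408079, minus strand) had 13 sense sites in IP 1 and 14 in IP 2, percentiles 92.2 and 90.8 for its span, and 1 shared intronic site with 2 mutated tags in each. Of the sense sites, 5 in IP 1 and 2 in IP 2 lay in exons and the rest in introns. A copy without introns could not give the intronic sites. Genes of the PARP family and of ADP-ribose turnover were named in both IPs in 20 of 23 cases (87.0%, Fisher's exact adjusted p = 0.00786), and against span-matched lists (mean 71.6%) the permutation adjusted p was 0.143, with 0.0154 for IP 2 alone and 0.400 for IP 1 alone. The span-matched difference turned to -3.16 points with a shared site required and to -1.06 with exon sites only (permutation adjusted p = 1.0 each), and fell to 5.44 against genes named in either IP (0.794). The ADP-ribose hydrolase MACROD1 had 37 and 41 sense sites, MACROD2 had 175 and 258 over a span of 2057829 bases, and PARP14 had 11 in each IP. MACROD1, MACROD2 and PARP14 were at percentiles 94.8, 66.9 and 86.2 in IP 1 and 93.3, 72.6 and 82.3 in IP 2. The lists hold no measure of the abundance of these transcripts.

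DNA repair genes were named in both IPs in 35 of 38 cases (92.1%, Fisher's exact adjusted p = 2.3e-05), above a span-matched mean of 71.7% (permutation adjusted p = 0.00512). The excess over span was not called with exon sites only or against genes named in either IP (permutation adjusted p = 0.161 each), nor with a shared site required (0.285). The ligase LIG1 had 20 sense sites in IP 1 and 21 in IP 2, the checkpoint kinase ATM 21 and 18, the recombination factor XRCC2 14 and 12, and the repair polymerase POLB 4 and 4. MDC1, the member named in neither IP, lies in the same stretch of chromosome 6 as DDR1.

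Genes for splicing and RNA-binding factors were named in both IPs in 31 of 40 cases (77.5%, Fisher's exact adjusted p = 0.0108), above a span-matched mean of 55.1% (permutation adjusted p = 0.00587). With IP 2 alone (permutation adjusted p = 0.165), with a shared site required (0.287) and against genes named in either IP (0.0789), their excess over span was not called. HNRNPK had 5 sense sites in each IP, SRSF4 4 and 11, SRSF10 4 and 1, and SON 9 and 10. HNRNPA1 and TAF15 were named in neither, although 6 and 7 sense-strand sites lay within the annotated span of TAF15. Ribosomal protein genes, most of them short, were named in both in 36 of 61 cases (59.0%, Fisher's exact adjusted p = 0.608). Span-matched lists had a mean of 25.2%, below the ribosomal protein genes (permutation adjusted p = 0.0016, from the smallest p-value that 10000 lists can give), a difference of 33.9 points. It fell to 10.1 points with a shared site required (permutation adjusted p = 0.0171) and to 4.07 with exon sites only, where it was not called (0.515). RPLP0 had 3 sense sites in IP 1 and 2 in IP 2, RPL22 3 and 5, and RPL11 2 and 3, while RPL6 and RPL7A were named in neither.

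Housekeeping and cytoskeletal genes were named in both IPs in 26 of 34 cases (76.5%, Fisher's exact adjusted p = 0.0238), above a span-matched mean of 43.5% (permutation adjusted p = 0.0016, again from the smallest p-value). Their excess over span was called in all 7 alternatives and was lowest, at 21.3 points against 33.0, with a shared site required. The myosin heavy chain MYH9 had 32 and 39 sense sites, the pyruvate kinase PKM 8 and 11, the aldolase ALDOA 6 and 6, and the prolyl isomerase PPIA 4 and 6. TPI1 and TUBB were named in neither, and TUBB lies in the chromosome 6 stretch where 116 protein-coding genes in a row had no site.

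Abundant nuclear and small noncoding RNAs were named in both IPs in 5 of 30 cases (16.7%), against 9.43% of other noncoding genes (Fisher's exact adjusted p = 0.227) and a span-matched mean of 4.91% (permutation adjusted p = 0.0176). The span-matched call was not made with IP 2 alone (permutation adjusted p = 0.165), with a shared site required (0.562) or against genes named in either IP (0.166). The paraspeckle RNA NEAT1 had 8 sense sites in IP 1 and 5 in IP 2, MALAT1 had 3 in each, and RN7SK and RN7SL2 were named in neither. MALAT1 was named here outside the rule, after its values were seen. Genes of the mitochondrial chromosome were named in both in 3 of 13 protein-coding cases (23.1%), below other protein-coding genes (Fisher's exact adjusted p = 0.0352), and their span-matched mean was 5.51% (permutation adjusted p = 0.102, or 0.0064 with IP 2 alone and 0.00498 with an FDR below the most common). The 3 genes, MT-ND4, MT-ND5 and MT-CO3, had only opposite-strand sites in IP 2, and with sense sites only 0 of 13 genes were named in both (Fisher's exact adjusted p = 0.00032). Their span-matched difference of 17.6 points turned to -3.92 with sense sites only, -2.74 with exon sites only and -1.04 with a shared site required (permutation adjusted p = 1.0 each). The whole mitochondrial chromosome held 8 sites in IP 1 and 13 in IP 2. Replication-dependent histone genes, which are short and lack a poly(A) tail, were named in both in 4 of 23 cases (17.4%), below other protein-coding genes (Fisher's exact adjusted p = 0.000944). Against genes of like span (mean 11.2%) the permutation adjusted p was 0.589, and H1-2 and H1-3 were named in neither.

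The cell type lists asked which kidney transcripts the IPs hold. Proximal tubule genes were named in both IPs in 21 of 30 cases (70%, Fisher's exact adjusted p = 0.173), against a span-matched mean of 70.5% (permutation adjusted p = 1.0). With sense sites only they were named in both in 15 of 30 cases, against a span-matched mean of 65.4% (a difference of -15.4 points, permutation adjusted p = 0.113). The difference was -12.43 points with an FDR below the most common (permutation adjusted p = 0.237) and -9.38 with IP 2 alone (0.309). The cadherin CDH6 had 36 sense sites in IP 1 and 52 in IP 2, the bicarbonate cotransporter SLC4A4 33 and 51, EZR of the brush border 12 and 23, and the peptidase DPP4 6 and 8. Percentiles for span in IP 1 and IP 2 were 95.5 and 98.6 for CDH6 and 59.8 and 65.5 for SLC4A4. They were 87.1 and 97.6 for EZR and 52.4 and 54.5 for DPP4. The water channel AQP1 and the glucose transporter SLC5A2 were named in neither IP. Genes of other kidney cell types were named in both in 9 of 26 cases (34.6%, Fisher's exact adjusted p = 0.0619), below a span-matched mean of 66.3% (permutation adjusted p = 0.0032). That deficit of 31.7 points was 17.1 with exon sites only (permutation adjusted p = 0.0334), and was not called with a shared site required (permutation adjusted p = 0.250) or against genes named in either IP (0.0922). The endothelial gene PECAM1 had 2 sense sites in each IP, and WT1 of podocytes and UMOD of the thick ascending limb were named in neither. Genes of inflammation and NF-kB were named in both in 14 of 32 cases (43.8%, Fisher's exact adjusted p = 0.228; span-matched mean 39.9%, permutation adjusted p = 0.839). NFKB1 had 6 and 16 sense sites (percentiles 43.7 and 68.8) and VCAM1 1 in each (54.1 and 49.3), while NFKBIA and CXCL8 were named in neither. The span-matched differences of collagens, proximal tubule genes, inflammation genes and histones, none of them called, turned sign under at least 1 alternative. By Fisher's exact test 11 of the 16 lists differed from other genes of their class, but against the genes named in either IP as the background none did (0 lists, lowest adjusted p = 0.0842, with 5 lists at an unadjusted p under 0.05). With IP 2 alone 6 lists differed, and the calls of collagens, TGF-beta signalling, splicing factors, housekeeping genes and mitochondrial genes were lost.

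**Figure D3:**
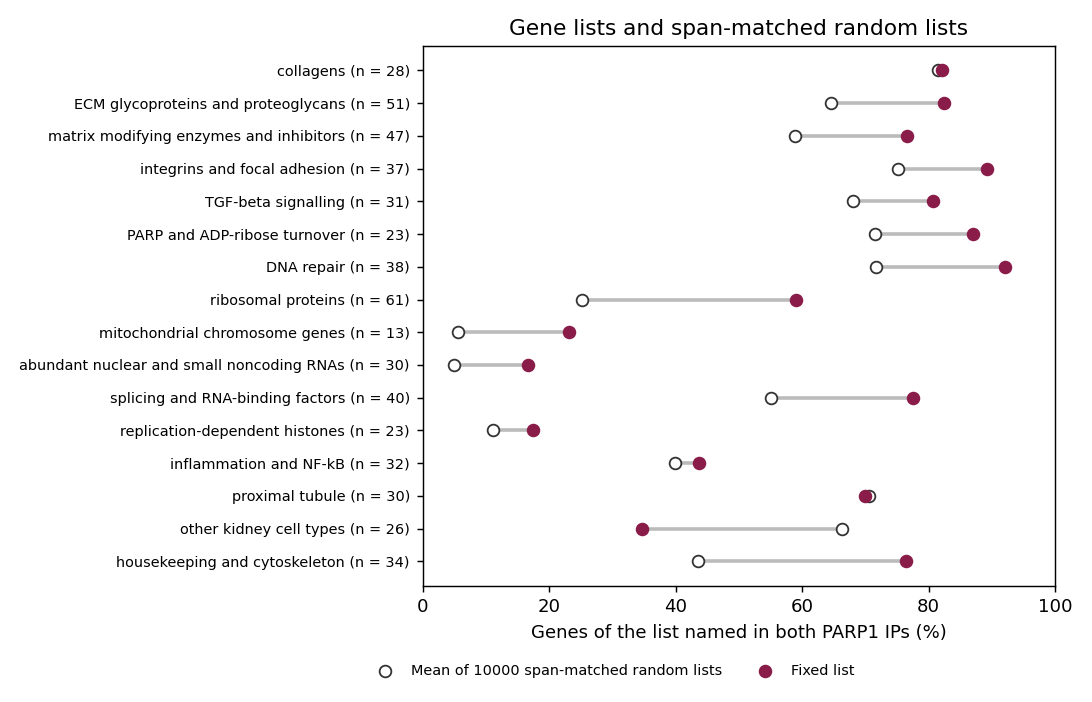
Share of the genes of each fixed list that were named in both PARP1 IPs (percent, filled points) beside the mean share of 10000 random lists of the same size matched on gene span (open points), with the number of genes in each list. Ribosomal protein genes stood at 59.0% against 25.2%, DNA repair genes at 92.1% against 71.7%, collagens at 82.1% against 81.5% and genes of other kidney cell types at 34.6% against 66.3%.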

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

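The settings with sense or exon sites only, 4 or more mutated tags, a window of 10 bases, mutation type, local shifts, FDR below the most common and span matching as a test, with all its alternatives, were chosen after the data were seen. No paired analysis was possible because the lists hold no input values. Unless said otherwise, list values are points above the background, with the adjusted p, and the cause of a change was not tested. The share of sites found in both IPs (IP 1 and IP 2) was 5.28% and 3.86% with strand ignored, 4.41% and 3.19% within 10 bases, 4.04% and 2.83% with 4 or more mutated tags in both, 3.13% and 3.14% with equal numbers of sites, and 3.07% and 2.30% with FDR below the most common. Placement on the chromosome put the shared share at 1001 times chance. With FDR below the most common, a setting that keeps mostly deletions and insertions, 7530 genes were named in both. Over all sites, 3340 genes had a shared site. With FDR below the most common, a filter that depends on the mutated tags themselves, the rank correlation of strength was 0.650. Introns then held 68.7% and 65.1%, intergenic sequence 13.5% and 17.1%, antisense sequence 6.33% and 7.96%, 3′ UTRs 5.47% and 4.84% and coding sequence 4.28% and 3.45%. Among sites in both IPs these were 70.4% and 70.4%, 12.9% and 12.9%, 5.58% and 5.59%, 4.64% and 4.65%, and 3.26% and 3.26%. With equal numbers IP 2 gave 57.5%, 24.6%, 11.5%, 2.96% and 2.15%. Span matching (a permutation test) left collagens at 0.688 (1.0), integrins at 14.1 (0.0675), TGF-beta at 12.6 (0.128) and PARP genes at 15.4 (0.143) without a call. It gave a call to ribosomal proteins at 33.9 (0.0016), noncoding RNAs at 11.8 (0.0176) and other kidney types at -31.7 (0.0032), and turned the sign of inflammation to 3.90 (0.839), proximal tubule to -0.526 (1.0), mitochondrial genes to 17.6 (0.102) and histones to 6.20 (0.589). Against genes named in either IP, a background of fewer genes, 0 of 16 lists passed Fisher's test (5 at an unadjusted p under 0.05), with DNA repair at 17.4, glycoproteins at 14.1, TGF-beta at 19.0 and integrins at 17.1 (0.0842 each), PARP genes at 9.75 (0.404), collagens at 14.8 (0.188), housekeeping at 12.5 and enzymes at 10.6 (0.198 each), splicing at 11.4 (0.207), mitochondrial genes at -34.4 (0.138), histones at -10.6 (0.666) and ribosomal proteins reversed at -5.24 (0.455). With a shared site required, PARP genes stood at 2.53 (0.818), collagens at 13.7 (0.115), mitochondrial genes at -14.9 (0.318), histones at -14.9 (0.0892) and splicing at 5.14 (0.424) without a call, and ribosomal proteins reversed at -0.113 (1.0). Exon sites left PARP genes at 2.78 (0.857), TGF-beta at 14.4 (0.0652), collagens at 10.4 (0.276), mitochondrial genes at -14.6 (0.317) and histones at -10.3 (0.317) without a call, called noncoding RNAs at 12.8 (0.000102), and reversed inflammation at 1.01 (0.857), proximal tubule at -1.28 (1.0) and ribosomal proteins at -3.15 (0.724). Sense sites called other kidney types at -31.6 (0.003) and reversed proximal tubule at -0.750 (1.0). With FDR below the most common, noncoding RNAs were called at 14.1 (0.00176) and other kidney types at -30.2 (0.00126), collagens at 8.90 (0.431) and mitochondrial genes at -10.9 (0.66) were not, and proximal tubule reversed at -0.636 (1.0). Leaving out each IP gave TGF-beta 15.0 to 22.4 (0.152 and 0.0179), collagens 20.1 to 24.2 (0.0624 and 0.0179), housekeeping 13.8 to 20.8 (0.152 and 0.0189), splicing 14.4 to 23.5 (0.132 and 0.00553), noncoding RNAs 2.80 to 16.8 (0.760 and 0.0189) and mitochondrial genes -38.5 to -11.8 (0.0169 and 0.520), with the call lost, or not made, where IP 2 alone was used. Without IP 1, 11 of the 16 lists kept their side of the threshold, and without IP 2, 15 did. The span-matched differences, with permutation adjusted p, changed as follows. A shared site in the gene left DNA repair at 11.8 (0.285), glycoproteins at 8.48 (0.287), noncoding RNAs at 2.70 (0.562), enzymes at 14.3 (0.0576), other kidney types at -13.7 (0.250) and splicing at 8.66 (0.287) without a call, called integrins at 25.1 (0.0096), and turned the sign of PARP genes to -3.16, inflammation to -2.65, mitochondrial genes to -1.04, histones to -1.99 (1.0 each) and proximal tubule to 6.36 (0.702). Against genes named in either IP, DNA repair stood at 11.3 (0.161), glycoproteins at 12.3 and other kidney types at -24.9 (0.0922 each), noncoding RNAs at 27.5 (0.166), enzymes at 13.4 (0.113) and splicing at 17.8 (0.0789) without a call, with inflammation reversed at -5.77 (0.794) and proximal tubule at 7.31 (0.693). Exon sites called integrins at 25.8 (0.0032), ended the calls of DNA repair at 12.7 (0.161) and ribosomal proteins at 4.07 (0.515), and reversed PARP genes at -1.06 and mitochondrial genes at -2.74 (1.0 each). Sense sites reversed collagens at -4.99 (0.754), mitochondrial genes at -3.92 and histones at -0.200 (1.0 each). FDR below the most common reversed collagens at -13.8 (0.237) and called mitochondrial genes at 21.2 (0.00498). Leaving out each IP gave collagens -2.23 to 1.37 and proximal tubule -9.38 to 1.49, neither called, PARP genes 10.98 to 19.96 and mitochondrial genes 11.5 to 40.9, called with IP 2 alone (0.0154 and 0.0064), and enzymes 13.0 to 15.4, noncoding RNAs 9.55 to 22.3 and splicing 12.6 to 22.7, not called with IP 2 alone (0.0772, 0.165 and 0.165). Overlap by 50% is the same as overlap for sites of 1 base and tests nothing, and the share of bases covered moved no region share beyond its interval.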

Other observations

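The tests of the opposite strand, chance coincidence, gene length (all 3), tags counted in pairs, the longest genes, the remaining neuronal genes and short genes were chosen after the results were seen, as were the regions of chromosomes 6 and 17. The test of gene length by rank correlation was written first as a test of length alone and renamed a test of contribution after its value was seen. The list of neuronal genes was written after NLGN1, MDGA2 and RIMS2 had been seen among the genes with most sites, and the chromosome 17 test was written after runs of genes without sites, 2 of them elsewhere on chromosome 17, had been seen.

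Genes named in 1 IP alone with the strongest sites were mostly processed pseudogenes, whose reads can be shared with the parent gene. In IP 1 these were NME2P1 and ENTR1P2, with up to 8 mutated tags, and the coding gene C7orf25, also with 8. In IP 2 they were AKR1B1P2 with 17, PABPC1P4 with 16 and the peroxiredoxin gene PRDX5 with 11. The strongest intergenic site in both IPs had 20 of 20 tags mutated in IP 1 and 14 of 15 in IP 2, and the next 4 had 5 of 6 and 6 of 9, 5 of 5 and 7 of 9, 5 of 25 and 4 of 34, and 4 of 9 and 4 of 6. The kidney injury marker HAVCR1 had 12 sense sites in IP 1 and 13 in IP 2, percentiles 96.9 and 96.8 for its span, and the tubule transcription factor PAX8 had 23 and 21, percentiles 98.0 and 94.5; both were picked after their values were seen.

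The same bases recurred in the 2 IPs, at 4.17% of the sites of IP 1. Coincidence of positions is argued against, since the share of 4.1715% exceeded the highest of 100 local shifts, 0.0277%. Bases of IP 1 were listed on the opposite strand in IP 2 250.74 times as often as after local shifts, so strand-independent mismatches, such as sequence variants of the cell line, may account for part of the recurrence. Among 18 shared substitutions with 10 or more tags in both IPs, 38.889% (interval 17.3 to 64.3) had 30% or more of tags mutated in both, between the bounds set for and against variant alleles, and the 18 sites are too few to decide. Whether PARP1 contact with RNA leaves mutations at fixed bases was not tested, since the inputs were not analysed here. The protocols describe no crosslinking step, so a mutated base is not by itself a sign of contact.

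Introns held most sites, at a lower density than exons, and the genes with most shared sites were mostly long. Genomic DNA, which would give both strands alike, is argued against as the whole cause by a sense to antisense ratio of 4.9383 in IP 2 (interval 4.84 to 5.04) and 7.52 in IP 1 over the 1996 longest protein-coding genes. The ratios of 7.5167 over the 10 genes with most shared sites and 2.3939 over 20 long neuronal genes in IP 2 decide nothing, since those sets held genes picked for their sites. Without NRXN3 and the 3 genes seen beforehand the neuronal ratio was 1.394 in IP 2 (interval 1.22 to 1.60) and 2.04 in IP 1. NRXN3 was not among the genes seen beforehand and had 118 sense and 8 antisense sites in IP 1 and 176 and 33 in IP 2. Leaving it out lowers the ratio, so that ratio decides nothing either. For such genes DNA stays open and its share was not measured. Gene length may contribute, with a rank correlation of 0.60885 (IP 1) and 0.65544 (IP 2) between span and sense sites, but length alone is argued against by a median rank correlation of 0.70795 (quartiles 0.539 and 0.847) between the sense sites of the IPs within 100 narrow bins of span, while percentile 0.01 of the genes of other kidney cell types among span-matched lists decides nothing, since that list was picked for its deficit. Whether nascent transcripts near PARP1 on chromatin give such sites is a hypothesis that was not tested, and transcription in this cell line, with or without PARP1 contact, stays open.

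Most sites had 2 tags, both mutated. That 1 fragment was counted as 2 tags may account for part of them, since substitutions with 4 of 4 tags mutated were 2.1 times the geometric mean of those with 3 of 3 and 5 of 5 in IP 1 and 2.1778 times in IP 2. Errors that do not recur stay open: substitutions with 2 of 2 recurred at 3.98% in IP 1 and 2.72% in IP 2, against 13.7% and 11.3% for those with 4 or more mutated tags, and the higher ratio of 0.28942 lay between the bounds set for and against them. No biological explanation was tested for this pattern.

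Among genes lying between 29656981 and 33329286 on chromosome 6, sites were found in 3 of 154 genes, against 82.1 expected from span, or 3.6525% of that number. From 45620344 to 46579682 of chromosome 17, 12.5% of 8 long genes had a site (KANSL1, with 2 sites in IP 2), against 7.31 genes expected. The stretch tested there held 0 sites in IP 1 and 2 in IP 2, against 178 and 204 in the equal stretch before it and 149 and 169 in that after it. No site was found in the 36 genes from OR5D18 to OR5AK2 on chromosome 11.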
